A study of Gallus gallus with 15 samples.

How the data were processed

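RNA of the germinal disc region of the F1 follicle, the largest follicle of the ovary and the next to ovulate, was hybridised to 1-colour (Cy3) Agilent arrays, 1 array per hen. Per the labels' protocols, 10 ng of total RNA was labelled and 600 ng of labelled cRNA was loaded, each hen yielded 1.5 to 5 µg of RNA, and 16 RNA samples were purified. Data of 15 hens were analysed here. The deposited scanner files were made with Agilent Feature Extraction 10.7.3.1, per the file headers, which also name the genome build galGal3. They give intensity values per spot on a linear scale, background-corrected by that software, per the file headers. The authors' table of processed values is on a log2 scale. How it was made is not given in the sources used here. Its columns had medians between 6.61 and 6.62, and within each of the 15 arrays its probe order was that of the median signal minus the local background (Spearman rho 1). Its sign follows the signal, and its absolute centring stays unknown. No column of it was left unused.

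The group of each hen was taken from its title and description. The 2 fields agreed for 7 male-biased hens (hen23, hen24, hen35, hen41, hen67, hen69 and hen78) and 6 female-biased hens (hen34, hen54, hen70, hen96, hen102 and hen104). They named opposite groups for hen98 and hen99, which were therefore placed in no group and entered no group comparison except the 2 alternatives that follow one field. Each array is labelled as one hen, so hens were the replicates and p-values measure the spread between hens as labelled. The groups share no replicate numbers.

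The signal of each of the 43803 non-control spots was taken as log2, and the array's 75th percentile was subtracted. Spots with an outlier flag (4 to 25 per array) were left out, and the spots of the 50 probes with several spots were averaged, which gave 43603 probes. Saturated spots were kept. A probe was tested if it was well above background on at least 6 of the 13 arrays compared, which left 29760 probes. Alternatives that changed the hens used the size of their own smaller group. The tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3, female-biased minus male-biased, with no covariate and Benjamini-Hochberg adjustment over all probes at 0.05. All tests between groups were two-sided.

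Probes were named through the RefSeq transcript accession in the files and the gene table of assembly GRCg7b. This named 10458 of the 43603 probes, for 4655 genes, and left 33145 probes unnamed here, among them 17079 with an Ensembl transcript identifier. No probe matched several genes. That assembly differs from the build of the arrays, so it was used for names and for the chromosome that defines the Z chromosome list, and no coordinates were taken from it. Of the tested probes, 8448 were named, for 3860 genes. For gene lists, a gene was represented by its probe with the highest mean signal over all arrays.

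Before the data were examined, 24 gene lists, the tests, the alternatives and the rule for named genes were fixed. List members were matched by symbol or by an alias written in the list. Reference synonyms were not used, because several pointed to other genes; this was decided after the matches had been inspected. Lists needed 3 members past the filter, and 23 qualified. A list score is the mean over members of the log2 value minus its mean over the hens, and group differences were tested by an exact permutation over all 1716 splits of the 13 hens. Camera, with a preset correlation of 0.01, compared each list with all other genes, and was repeated with an estimated correlation. Fry was run as a further test of whether members move one way. The rule for named genes took the 12 genes with the smallest p in each direction, whether or not they passed the threshold, 2 to 4 members with the smallest p of each list, a fixed set of follicle and germ cell genes, and the genes detected in one group alone. A gene's named probe in the first part is that with the smallest p, so its p is the lowest of its probes. Of the genes this rule named, 4 are not reported here, and no others took their place.

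Slide, scan and array position were read from the files. The 2 slides coincided with the 2 scans, and each held both groups, so slide was tested as a block. Array row was not balanced: most male-biased hens compared were in row 1 and most female-biased hens in row 2. Alternatives covered the background correction (normexp with offset 50), the scaling, the authors' values, the filter, slide, row, array weights, the variance prior, the labels of hen98 and hen99 and each hen left out. The planned normexp alternative named the mean signal; that column was not used here and the median signal took its place. The array weights and the variance prior act on the limma fit alone and give no separate list scores. Calls of probes detected in one group alone used the software's flag and, as an alternative, the 99th percentile of the negative control spots. Fold bounds for such a probe set the brighter group's mean against the other group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Hens left out because they lie apart, and camera under the other settings, were added after seeing the data.

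The procedure was tested on simulated data with the means and residual spreads of the 29760 probes of this comparison. Of 50 probes each given a log2 change of 1, 2, 3 and 4, the fit called 18%, 76%, 90% and 100%, and it called 6 unchanged probes beside the 200 changed ones. Without any change, 5.06% of simulated probes had an unadjusted p under 0.05. The simulated probes were drawn independently of each other. These runs therefore do not show how far correlation between probes spreads such counts in the real data. The number of arrays limits the precision.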

Results

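The arrays measured maternal RNA in the germinal disc region, the small disc of oocyte cytoplasm with the follicle wall over it, of the F1 follicle of layer hens. Hens had offspring that were mostly male (male-biased, 7 hens) or mostly female (female-biased, 6 hens), and 2 further hens carried conflicting labels. The comparison asks whether RNA in this region differs between hens of opposite offspring sex ratio. The 75th percentile signal ranged from 473 to 1228 intensity units over the 15 arrays, and 58.9% to 70.1% of the probes were well above background.

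Most granulosa cell, steroid hormone and proliferation genes were detected in all 15 hens. Of 43603 probes, 23143 were well above background on every array and 8767 on none. Of 20 named granulosa cell markers, 18 were detected on every array, as were 11 of 12 steroid hormone synthesis genes and all 19 proliferation genes. Of 13 oocyte and germ cell markers, 7 were detected on every array and 4 on none. Theca and stroma markers were detected on every array for 5 of 16 genes, leukocyte markers for 7 of 21 and red blood cell markers for 4 of 12. The probes of CYP11A1, which makes pregnenolone from cholesterol, and of ZP3, an egg coat protein that avian granulosa cells secrete, were saturated on all 13 arrays compared. CYP19A1, GDF9 and DDX4 had no probe well above background on any of the 15 arrays, and ESR1 had one on 3.

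No probe differed between the groups after adjustment. The genes with the smallest p that were higher in female-biased hens were led by DLX6, a homeobox gene, with a log2 difference of 2.11 ± 0.33 (SE; 6 female-biased and 7 male-biased hens). SMIM5 followed with 1.61 ± 0.32, EFHC2 with 1.30 ± 0.26 and TBX18 with 1.79 ± 0.41. AMPD3 (1.28), LHX8 (1.68), MAB21L2 (1.37), HIST1H111R (1.64), FGF8 (1.26), NKX2-5 (2.34) and CBFA2T2 (0.88) were the others by log2 difference, and for each of these 11 genes all 6 female-biased hens lay above the male-biased median. Lower in female-biased hens were RBMS1, with a log2 difference of -1.39 ± 0.29, NHLRC2 with -1.10 ± 0.24, and CHIR-B4, an immunoglobulin-like receptor gene, with -1.51 ± 0.34. CLDN3, a tight junction protein, differed by -1.61, IL10RB by -1.67, AKR1E2 by -1.84, TMC3 by -1.80 and HMOX1, which degrades heme, by -3.83 ± 0.91 on the log2 scale. MATN3 (-2.72), PGD (-0.96), APCDD1 (-2.91) and ACVR2B (-0.96) completed the 12, and all 6 female-biased hens lay below the male-biased median for each of them except MATN3 (5 of 6). The female-biased SD of HMOX1 was 2.34 against 1.29 in male-biased hens, that of MATN3 1.80 against 0.69 and that of APCDD1 1.65 against 1.21. How far the differences of these 3 genes rest on single hens is not given here. All 23 had a limma adjusted p of 0.415. Several were dim: the DLX6 probe was well above background in 5 of 6 female-biased and 2 of 7 male-biased hens. In female-biased hens the probes of HMOX1, MATN3 and IL10RB were so in 2 of 6 and those of TMC3 and CHIR-B4 in 1 of 6, and in male-biased hens those of LHX8 in 2 of 7 and SMIM5 in 3 of 7, so these differences are partly against background. Another probe gave a log2 difference of 0.40 for EFHC2, 0.53 for TBX18, -0.41 for CHIR-B4 and -1.08 for AKR1E2, and the 3 probes of APCDD1 lay between -2.91 and -0.25.

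**Figure D1:**
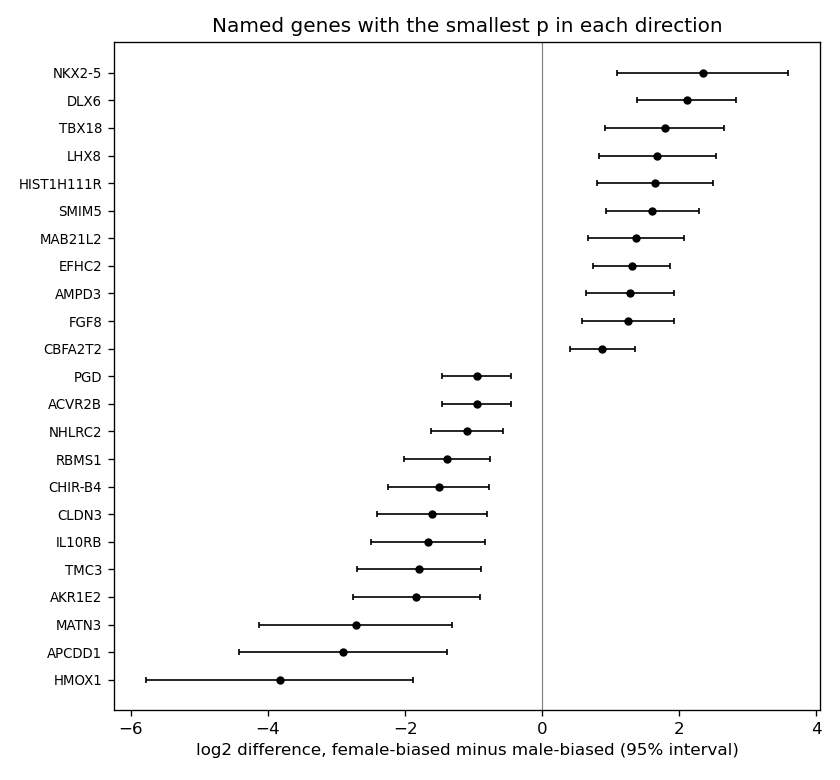
Log2 difference between female-biased (n = 6) and male-biased (n = 7) hens on the x axis for the named genes with the smallest p, 11 higher and 12 lower in female-biased hens, with 95% intervals of the limma fit that are not corrected for the choice of genes. The differences ran from -3.83 for HMOX1 to 2.34 for NKX2-5, and all had an adjusted p of 0.415.

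By limma, 0 of 29760 probes had an adjusted p under 0.05, the smallest adjusted p was 0.415, and 3041 probes (10.2%) had an unadjusted p under 0.05, against 1488 that a uniform distribution would give. Of these, 1565 were higher and 1476 lower in female-biased hens. With slide as a block the counts were 0 and 3138, and within slide 1 and slide 2 alone they were 2 and 2535, and 2 and 2355. With slide and row as blocks they were 0 and 2086, and array row was not balanced between the groups. The unadjusted count was 1434 with hen98 and hen99 placed by their description, 4287 with them placed by their title, and 1561 without hen54 and hen102.

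The arrays of hen54, hen98 and hen102 stood apart from the other 12 on the first principal component, which held 34.2% of the variance. Their scores were 99.8, 166 and 174, and those of the other 12 hens lay between -64.8 and 27.7. Both hen54 and hen102 are female-biased and hen98 carries conflicting labels. The 3 arrays came from both slides and all from array row 2, whose other 5 arrays lay with the rest.

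**Figure D2:**
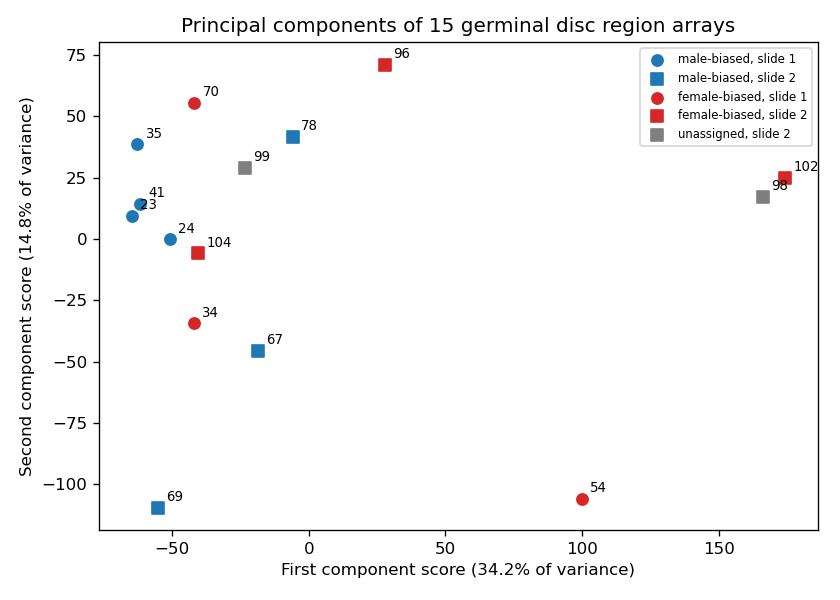
First and second principal component scores of the 15 arrays over 29659 probes, with the hen number beside each point, the colour giving the group and the marker the slide. The arrays of hen54, hen98 and hen102 lie at 99.8, 166 and 174 on the first component, and the other 12 lie at or below 27.7.

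Oocyte and germ cell markers were higher in female-biased hens for 7 of 8 measured members. None passed over all genes tested, and 6 had an adjusted p under 0.05 adjusted over the list alone. LHX8, an oocyte transcription factor, had the smallest p in the list, followed by DAZL, a germ cell RNA-binding protein, with 1.18 ± 0.34 (SE), CCNB3 with 1.02 ± 0.34 and MOS, the kinase that holds the mature egg in meiotic arrest, with 1.41 ± 0.48. BMP15, an oocyte growth factor, differed by 0.89 ± 0.36 and PIWIL1 by -0.95 ± 0.51. The list score was 0.46 ± 0.27 in female-biased and -0.39 ± 0.80 in male-biased hens (SD), a difference of 0.85 (exact permutation p = 0.0332, adjusted p = 0.253 over 23 lists). Camera ranked the list higher (adjusted p = 0.000334), a call not held with an estimated correlation (adjusted p = 0.66) or on slide 2 alone (adjusted p = 0.251).

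Genes of meiosis and chromosome segregation were higher in female-biased hens for all 17 measured members, 7 of them at an unadjusted p under 0.05. MOS is a member of both this list and the oocyte list, so these lists overlap. CENPA, the centromere histone, differed by 1.16 ± 0.31 (SE) and passed adjusted over the list alone. CDC20 differed by 0.77 ± 0.28 and BIRC5 by 0.73 ± 0.29. The list score differed by 0.63 (exact permutation p = 0.021, adjusted p = 0.241), and camera ranked the list higher (adjusted p = 1.75e-05; adjusted p = 0.66 with an estimated correlation). Proliferation genes were higher for 17 of 19 members, with CDK1 at 0.98 ± 0.31, RRM1 at 0.69 ± 0.23, RFC4 at 0.74 ± 0.27 and TOP2A at 0.69 ± 0.29. Their score differed by 0.45 (exact permutation p = 0.0752, adjusted p = 0.253), with a camera adjusted p of 0.000634 and an adjusted p of 0.66 with an estimated correlation. Without male-biased hen78, the score of oocyte and germ cell markers differed by 1.11, the score of meiosis and chromosome segregation by 0.78 and the score of cell proliferation by 0.63, each with an adjusted p of 0.0166 by exact permutation, where the adjusted p over all alternatives ran from 0.0166 to 0.885, 0.885 and 1. At the other end, male-biased hen41 had the lowest oocyte, meiosis and proliferation scores of the 15 hens (-1.52, -1.04 and -1.03). The differences with all hens therefore rest in part on hen41. Without it the camera calls of these lists were held (adjusted p = 0.00223, 0.000412 and 0.0123). On slide 2 alone the camera calls of the meiosis and the proliferation list were not held (adjusted p = 0.164 and 0.618).

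Theca and stroma markers were lower in female-biased hens for 10 of 11 measured members, 4 at an unadjusted p under 0.05 and none past adjustment over all genes or adjusted over the list alone. ACTA2, a smooth muscle actin, differed by -1.58 ± 0.57 (SE), COL6A3 by -1.90 ± 0.70, POSTN, a matrix protein, by -1.86 ± 0.78 and COL3A1 by -1.17 ± 0.53. FN1, a further member, was saturated on all 7 male-biased and 2 female-biased arrays, so its difference is not given. FN1 still enters the count and the score. The score was -0.54 ± 0.83 in female-biased and 0.46 ± 0.29 in male-biased hens (SD), a difference of -0.997 (exact permutation p = 0.0035, adjusted p = 0.0804). Camera ranked the list lower (adjusted p = 0.00227; adjusted p = 0.508 with an estimated correlation and 0.294 with probes well above background on all 13 arrays). The score of theca and stroma markers differed by -0.31 with that filter and by -0.50 after normexp. ACTA2 and POSTN were well above background in 3 of 6 female-biased hens. Relative to the mean of all 15 hens, the scores of hen54, hen98 and hen102 were -1.34, -1.31 and -1.70, and the other 12 hens lay at -0.05 or above. The leukocyte scores of these 3 hens were also the lowest, at -0.87, -0.69 and -0.72 against -0.43 or above. Without hen54 and hen102 the difference was -0.47 (exact permutation p = 0.0212), with COL6A3 at -0.95, POSTN at -0.50 and COL3A1 at -0.53. Within slide 1 it was -0.72 (exact permutation p = 0.0857) and within slide 2 -1.33 (exact permutation p = 0.1, the smallest that 3 against 3 hens allow).

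**Figure D3:**
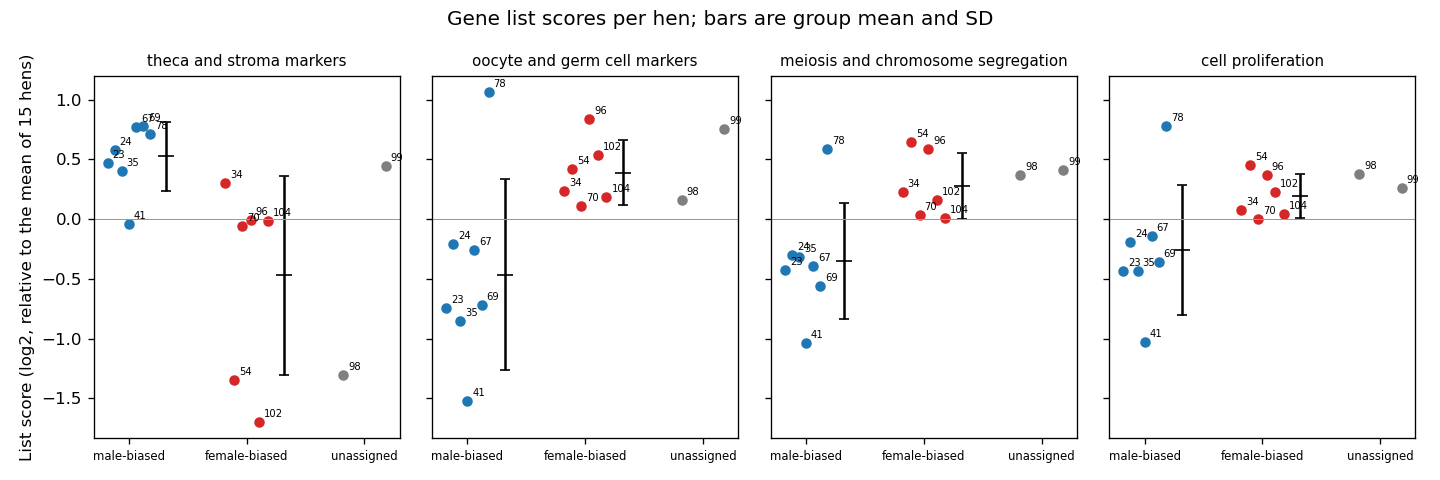
List scores per hen, as the mean log2 value of the members relative to the mean of the 15 hens, for the 4 lists that camera called with its preset correlation (0 lists with an estimated one), with hen numbers beside the points and bars for mean and SD of each labelled group. The arrays of hen54, hen98 and hen102 have the lowest theca and stroma scores, and male-biased hen41 and hen78 have the lowest and highest oocyte scores, -1.52 and 1.06.

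Granulosa cell markers were higher for 14 of 19 members and steroid hormone synthesis genes for 8 of 11, with no member past either adjustment. These counts and both list scores include members with saturated probes, among them ZP3 and HSD3B1, whose direction says nothing on expression. Among the granulosa markers, INHBB, well above background in 2 of 6 female-biased hens, differed by -1.46 ± 0.48 (SE), CDH2, a cadherin, by 0.58 ± 0.21, GJA1, a gap junction protein, by 1.02 ± 0.42 and AMH by 0.77 ± 0.32. HSD17B1, which makes active estrogens and androgens, differed by 1.26 ± 0.45, and STAR, which brings cholesterol into mitochondria, by -0.99 ± 0.47, and by -0.47 without hen102. Its probe was saturated on 1 male-biased array. NR5A2 differed by 1.40 ± 0.75. Without hen54 and hen102, STAR differed by -0.34, NR5A2 by 0.48 and GJA1 by 0.51. CYP17A1 (0.37) and FST (-0.28) had log2 differences within 2 standard errors of 0, and without hen54 and hen102 they differed by 0.080 and 0.30, and FST by 0.15 with array weights. So had FSHR (0.53) and NR3C1 (0.38), but the other probe of FSHR gave -0.62, the 4 probes of NR3C1 lay between -0.09 and 0.38, and NR3C1 differed by -0.63 on slide 1 alone. The probes of HSD3B1, LHCGR and INHA were saturated on part of the arrays of both groups, so their differences are not read. The score of granulosa cell markers differed by 0.22 (exact permutation p = 0.115) and that of steroid hormone synthesis by 0.29 (exact permutation p = 0.0769). Camera called neither list with all 13 hens (adjusted p = 0.162 and 0.301). On slide 2 alone it called both higher (adjusted p = 0.00668 and 0.0257), and on slide 1 alone it ranked both lower (adjusted p = 0.796 and 0.769). It also called granulosa cell markers higher without hen54 (adjusted p = 0.0386).

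Of 23 hormone and yolk receptor genes, 10 were higher in female-biased hens. VLDLR, the oocyte receptor that takes up yolk lipoprotein, differed by 1.18 ± 0.42 (SE), with all 3 of its probes between 1.10 and 1.27. THRB, well above background in 2 of 6 female-biased hens, differed by -1.35 ± 0.60, PRLR by -0.77 ± 0.37 and PGR, the progesterone receptor, by -1.87 ± 1.15. Without hen54 and hen102, PGR differed by 0.089, VLDLR by 0.65, THRB by -0.63 and PRLR by -1.27. Of 31 TGF-beta and BMP signalling genes, 19 were higher. ACVR2B and SMAD9 (1.62 ± 0.43) passed adjusted over the list alone, and the score of TGF-beta and BMP signalling differed by 0.11 (exact permutation p = 0.502), and by 0.19 without hen54 and hen102. Among 14 genes of matrix turnover and prostaglandins, MMP2 (1.24 ± 0.34), well above background in 3 of 7 male-biased hens and so partly against background, passed adjusted over the list alone, PTGS2, the inducible prostaglandin synthase, differed by -1.67 ± 0.59, and by -0.75 without hen54 and hen102, and PLAU by 1.32 ± 0.52. The score of extracellular matrix turnover and prostaglandins differed by -0.10 (exact permutation p = 0.613), and by 0.18 without hen54 and hen102.

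The remaining lists had no member past either adjustment. For cholesterol synthesis and uptake the score differed by -0.14, with DHCR7 at -0.64. It differed by -0.16 for hormone and yolk receptors, by -0.26 for red blood cell markers, with CA2 at -1.96, and at 0.19 without hen54 and hen102, and HBA1 at -0.41, and by -0.43 for leukocyte markers, with CD3D at -0.95 and IRF8 at 0.89. Endothelial markers differed by 0.10, with SOX18 at 0.94 and KDR at -0.29, and microtubule motors by 0.10 with KIF18B at 1.08 and DYNC1LI2 at -0.55. Insulin, IGF and mTOR signalling differed by 0.20, with PIK3CB at -0.49. The probe of IGFBP4 was saturated on 2 of 6 female-biased arrays, so its difference is not read. The glucocorticoid response differed by -0.28, with CEBPB at -1.26 and FKBP5 at -0.42, and the heat shock and unfolded protein response by -0.24, with DNAJC3 (saturated on 1 female-biased array) at -0.74 and HSPB1 at -1.31. Immediate early genes differed by less than 0.01 in size, with MYC at 0.50, apoptosis and lysosome genes by -0.16, with FAS at -1.93, and sex determination genes by 0.37, with WT1 at 0.95. Ribosomal proteins differed by -0.04, with RPL7L1 at -0.57, and oxidative phosphorylation by -0.03, with NDUFA12 at 0.45. The 171 Z chromosome genes differed by -0.05, with MELK at 0.99, F2RL1 at -2.79, CFC1 at -2.33 and FOCAD at -1.09. The F2RL1 probe was well above background in 2 of 6 female-biased hens, and the 4 probes of FOCAD lay between -1.25 and -0.08. The female-biased SD was 2.37 for F2RL1 and 1.67 for CFC1, against 0.88 and 1.33 in male-biased hens. How far the differences of these genes rest on single hens is not given here. Without hen54 and hen102, HBA1 differed by -0.67, KDR by -0.44, PIK3CB by -0.29, CEBPB by -0.46, DNAJC3 by -0.39 and RPL7L1 by -0.37. Without both hens the score of leukocyte markers differed by -0.13, the score of red blood cell markers by -0.049, the score of heat shock and unfolded protein response by -0.0079, the score of glucocorticoid response by 0.0067, the score of cholesterol synthesis and uptake by -0.0051, the score of hormone and yolk receptors by -0.063, the score of immediate early genes by 0.22, the score of sex determination genes by 0.59 and the score of oxidative phosphorylation by -0.092. The probe of FAS was well above background in 3 of 6 female-biased hens. Adjusted p values of these scores by exact permutation ran from 0.253 to 0.998. For 3 of these lists the median of the members' log2 differences had the other sign than the score: 0.05 for red blood cell markers, -0.15 for endothelial markers and 0.01 for ribosomal proteins. Camera gave sex determination genes an adjusted p of 0.0982 (0.66 with an estimated correlation), and called them higher without hen54 and hen102 (adjusted p = 0.00185), by description (0.0109), on slide 2 alone (0.0145), with slide and row as blocks (0.0495) and without hen35, hen54, hen78 or hen102, with adjusted p values up to 0.46 over all alternatives at the preset correlation. Without hen96, which had the highest score (0.99), the camera adjusted p of sex determination genes was 0.303. Camera also called cholesterol synthesis and uptake lower on slide 1 alone (adjusted p = 0.00116) and with slide and row as blocks (0.0495). It called the heat shock list lower on slide 1 alone (0.00504), with both blocks (0.0495) and after normexp (0.0498). It called leukocyte markers lower without hen41 (0.0476) and without hen96 (0.0195). The sign of KDR turned after normexp, and those of the score of oxidative phosphorylation and the score of immediate early genes after quantile normalization. The W chromosome list had 1 measured gene and was not tested.

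One probe was well above background in one group alone, in all 7 male-biased and none of the 6 female-biased hens. It targets an unnamed transcript, and its signal was at least 1.36-fold higher in male-biased hens (limma adjusted p = 0.415).

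Across all 15 hens, the SD of the list score was 0.81 for theca and stroma and 0.72 for oocyte and germ cell markers, against 0.27 for granulosa cell markers and 0.09 for Z chromosome genes. Of 15 pairs among 6 cell type lists, none had a correlation past adjustment. Because theca scores fell into separate clusters, its pairs were computed over the 12 hens that lie together. Oocyte and endothelial markers had Pearson's r = 0.66 (permutation p = 0.00821, adjusted p = 0.123), Spearman's rho = 0.61 (permutation p = 0.0168, adjusted p = 0.132), r = 0.61 without the 2 hens farthest from the median, and r = 0.53 and 0.51 within slides 1 and 2.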

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

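The tests of hen54, hen98 and hen102 against the other 12 arrays, of the theca difference, of the oocyte and proliferation scores and the splits for both limma counts were chosen after the result was seen, and COL1A2, COL5A1, CYP17A1 (in these 3 hens) and TAGLN were named after their values were seen. Within the groups of 6 and 7 hens, 288 sets of values (array measures, list scores and named genes) were searched for a hen far from the others, and 15 stood out, where chance flags about 1 in 20, or 14.4. The total is near that number, but most flags among female-biased hens fell on hen102, so it does not show that the flags are chance. The search uses the gap to the nearest hen. Hens far out on the same side, such as hen54 and hen102 on the first component, can therefore hide each other. Among female-biased hens, hen102 was lowest for STAR (1.78, nearest hen 4.44), INHBB (-7.79), COL3A1 (-6.83), TNFRSF1A (-3.56) and RPL7L1 (2.87), and highest for FOXO1 (1.40) and MAB21L2 (-0.99), as log2 values relative to the array's 75th percentile. In the same group, hen54 was lowest for NHLRC2 (-2.76) and hen104 highest for the cholesterol synthesis and uptake score (0.75). Among male-biased hens, hen78 was highest for AMPD3 (-3.33), MOS (-1.19), BIRC5 (3.92) and RFC4 (3.37), and hen69 highest for THRB (-3.06) and RPL19 (6.01).

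The arrays of hen54, hen98 and hen102 lay apart on the first component. Array signal or detection is argued against as the source in all 3, since 0 of 4 array measures put all 3 arrays outside the range of the other 12. The array of hen54 did lie above them in 75th percentile signal (1228 against at most 1110), in the share of probes well above background and in saturated probes (374 against at most 332). RNA quality was not measured. Slide or row as the whole source is argued against as well, since at least 5 other arrays shared each slide and row with one of them and lay with the rest. All 3 arrays were in array row 2, so a part played by the row stays open. An even loss of theca and stroma cells would lower all 11 measured members, if their RNA per cell was the same in all hens. Below the other 12 hens lay 4 of the 11 in hen54, 6 in hen98 and 7 in hen102, and 3 (COL6A3, POSTN and TAGLN) in all 3 hens. ACTA2 and COL5A1 are near background and can show little. CYP17A1, a steroid enzyme of theca cells, was above the other 12 in all 3 hens (-3.52, -2.58 and -2.70 against at most -3.57), and COL1A2, the collagen of highest signal in the list, was 2.87 and 3.29 in hen98 and hen102, within the range of 1.66 to 3.54 of the other 12, and 0.93 in hen54, below it. An even loss too small to bring a member below all 12 would escape this count. In hen98 and hen102 the CYP17A1 and COL1A2 values argue against an even loss as large as the fall of TAGLN (-7.45 and -7.35 against at least -1.045). That holds only if the RNA of CYP17A1 and COL1A2 per cell was not raised in these hens, which was not tested. In hen54 an even loss stays open, since COL1A2 was low and CYP17A1 lay only just above the others. A loss of part of these cells stays open in all 3 hens. Leukocyte scores were also lowest in the 3 hens (-0.87, -0.69 and -0.72). The design names no group that matches these 3 hens; a hypothesis on follicle stage stands under the other observations.

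The theca and stroma score was lower in female-biased hens by -0.997, not past adjustment (exact permutation adjusted p = 0.0804). Slide alone is argued against, since the smaller of the differences within slides was -0.72, in the same direction as the other. Without hen54 and hen102 the difference was -0.47, only just under the bound of 0.5 of its size set for these hens as the main source, so much of the difference may rest on them, and the rest is open. The offspring sex ratio itself also stays open.

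Camera with its preset correlation ranked the oocyte, meiosis and proliferation lists higher in female-biased hens. These calls were lost with an estimated correlation (adjusted p = 0.66 for each) and on slide 2 alone (adjusted p = 0.251, 0.164 and 0.618), and held on slide 1 alone (adjusted p = 7.39e-06, 2.09e-07 and 2.70e-07). Slide 2 holds male-biased hen78, which had the highest oocyte score (1.06). Slide 1 holds male-biased hen41, which had the lowest (-1.52). No score passed exact permutation over the 13 hens (adjusted p = 0.253, 0.241 and 0.253), while without hen78 the score of oocyte and germ cell markers, the score of meiosis and chromosome segregation and the score of cell proliferation each did (adjusted p = 0.0166, and up to 0.885, 0.885 and 1 over all alternatives). Whether the groups differ therefore stays open. A candidate explanation for these ranks is that the dissected pieces held different shares of oocyte material: over the 15 hens the oocyte and proliferation scores, which share no gene, had Pearson's r = 0.96 and Spearman's rho = 0.91 (permutation p = 1e-05 for each, the smallest the resampling gives; 1 relation tested), r = 0.92 without the 2 hens farthest from the median, and r = 0.98 and 0.90 within slides. Within the labelled groups r was 0.97, so the relation does not come from the group difference. This does not tell a difference in dissection from a difference in the oocyte's own RNA. The relation also cannot show that oocyte material is the source, since anything that moves both lists together would give it. A larger oocyte share could be expected to lower the share of granulosa cells. The oocyte and granulosa scores had Pearson's r = 0.39 (permutation p = 0.154, adjusted p = 0.386), so no such fall was seen.

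Chance cannot be excluded for 3 of the 4 counts, and the other decides nothing. Of 100 splits of the 13 hens into groups of 7 and 6, the real one included, 15 gave at least the 3041 probes with an unadjusted p under 0.05, and the highest other split gave 5291. The 47 other splits that kept hen54 and hen102 in 1 group gave a median of 1710 such probes, and the 52 that parted them 929.5. All 100 splits gave at least the 0 probes past adjustment (highest other 1), as any split must, 29 gave at least the 1 probe detected in one group alone (highest other 12), and 42 gave at least the 4 lists that camera called (highest other 10).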

How the results depend on the processing

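Leaving out hen54 and hen102 together, and camera under the settings other than the fit reported, were chosen after seeing the data; the other alternatives were planned. Past an adjusted p of 0.05 by limma there were 0 probes in the fit reported (3041 at an unadjusted p under 0.05) and under every scaling, background, filter, slide block, array weight, variance prior and label alternative, 2 on slide 1 alone, 2 on slide 2 alone, and 0 to 1 with each hen left out (1 without hen70). Without hen78, 330 probes had an adjusted p under 0.1, against 0. The count of probes past unadjusted p of 0.05 stayed within 1.5 times of 3041 except with hen98 and hen99 placed by description (1434, against 4287 by title) and without hen54 and hen102 (1561), and ran from 2086 (without hen102) to 4187 (without hen70) with each hen left out. The share of them higher in female-biased hens was 51.5%, and 63.9% with slide and row as blocks, 62.4% by description and 40.6% without hen54 and hen102. The gene list scores gave 0 lists past exact permutation, 1 without the filter and 1 by title (theca and stroma in both), and 0 to 4 with each hen left out (1 without hen41, 4 without hen78). The gene list ranks gave 4 lists by camera, 8 with slide and row as blocks, 9 on slide 1 alone, 0 with an estimated correlation, 0 by fry, and 4 to 6 with each hen left out. On slide 2 alone camera called 6 lists, of which theca and stroma (adjusted p = 0.00698) was the only 1 of the 4 called in the fit reported, while oocyte (adjusted p = 0.251), meiosis (0.164) and proliferation (0.618) were lost. With probes detected on all 13 arrays it called 3, without theca and stroma (adjusted p = 0.294). The probes well above background in one group alone numbered 1, and 5 by the negative controls, 61 on slide 1, 497 on slide 2, 0 by description, 4 without hen54 and hen102, and 1 to 6 with each hen left out (6 without hen34, 4 without hen54, 3 without hen96, 3 without hen104 and 2 without hen35). The slide counts rest on fewer hens, among which such patterns arise more often. The cause of the other shifts was not tested. The score of theca and stroma markers differed by -0.997, by -0.50 after normexp, -0.31 with probes detected on all 13 arrays, -0.64 by description and -0.47 without hen54 and hen102, with adjusted p values between 0.0179 and 0.575 over all alternatives by exact permutation. HMOX1 had an adjusted p of 0.0402 by limma on slide 2 alone (log2 difference -5.79), and between 0.0402 and 0.991 over all alternatives. The correlated pairs of cell type lists numbered 0 of 15 and 0 under each of their 3 alternatives. Of these, 1 left out genes held by 2 compared lists, of which there were 0, so it only repeats the main result. By the negative controls 23335 probes were detected on every array, against 23143 by the flag. Array weights and the variance prior were not run for list scores and camera. Of 3222 values of named genes 3176 kept direction and side of the threshold, as did 598 of 644 list scores.

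The log2 difference changed sign in 45 values of named genes and 39 list scores, none called by limma or exact permutation in either setting, and the cause was not tested. Camera did call ribosomal proteins, higher on slide 2 alone (adjusted p = 0.00153), and lower on slide 1 alone (adjusted p = 7.39e-06) and with slide and row as blocks (adjusted p = 0.00153). Camera also called other lists whose score turned between settings. It called TGF-beta and BMP signalling higher on slide 2 alone (adjusted p = 0.0073). On slide 1 alone it called cholesterol synthesis and uptake and hormone and yolk receptors lower (adjusted p = 0.00116 and 0.024). All these calls use the preset correlation of 0.01. The estimated correlation of ribosomal proteins was 0.416, with which their adjusted p was 0.893 in the fit reported. The probes of CYP11A1, ZP3 and NPC2 were saturated on all 13 arrays and those of HSD3B1, LHCGR, INHA and RPL36 on part of them, so their sign changes say nothing on expression. After normexp this held for ERG (0.062) and KDR (0.040). After quantile normalization this held for INHA (0.091), the score of immediate early genes (0.0032) and the score of oxidative phosphorylation (0.0035). After median scaling this held for INHA (0.013) and the score of immediate early genes (0.029). With the authors' values this held for NPC2 (-0.0054), RHCE (-0.0094), CYP11A1 (-0.053), the score of immediate early genes (0.013) and the score of oxidative phosphorylation (0.0038). With probes detected on all 13 arrays this held for the score of hormone and yolk receptors (0.10) and the score of Z chromosome genes (0.010). With slide and row as blocks this held for NPC2 (-0.034), HBAD (-0.014), RHCE (-0.061), CYP11A1 (-0.030), LHCGR (-0.15) and the score of immediate early genes (0.00032). On slide 1 alone this held for NPC2 (-0.41), HBA1 (0.095), RHCE (-0.050), KDR (0.37), CYP11A1 (-0.40), HSD3B1 (-0.21), LHCGR (-0.49), NR3C1 (-0.63), ZP3 (-0.42), the score of TGF-beta and BMP signalling (-0.21) and the score of insulin, IGF and mTOR signalling (-0.021). On slide 2 alone this held for HBAD (-0.070), RPL36 (0.29), INHA (0.69), the score of cholesterol synthesis and uptake (0.19), the score of hormone and yolk receptors (0.048), the score of endothelial cell markers (-0.0081), the score of immediate early genes (0.16), the score of ribosomal proteins (0.34) and the score of oxidative phosphorylation (0.046). With array weights this held for RHCE (-0.046) and FST (0.15). With hen98 and hen99 placed by title this held for the score of ribosomal proteins (0.028) and the score of oxidative phosphorylation (0.0014). With hen98 and hen99 placed by description this held for RHCE (-0.019), KDR (0.092), HSD3B1 (-0.0071), LHCGR (-0.012), INHA (0.066) and the score of immediate early genes (0.094). Without hen54 and hen102 this held for PGR (0.089), CA2 (0.19), RHCE (-0.34), INHA (0.049), FST (0.30), the score of glucocorticoid response (0.0067), the score of immediate early genes (0.22) and the score of extracellular matrix turnover and prostaglandins (0.18). With the mean over all probes of a gene this held for the score of endothelial cell markers (-0.017). With the score of each hen taken as the median over the members this held for the score of immediate early genes (0.12). With each hen left out in turn, the log2 difference ran for INHA from -0.20 to 0.095, for the score of immediate early genes from -0.12 to 0.15, for the score of ribosomal proteins from -0.12 to 0.033, for the score of oxidative phosphorylation from -0.089 to 0.020, for RHCE from -0.10 to 0.37, for the score of extracellular matrix turnover and prostaglandins from -0.21 to 0.022 and for LHCGR from -0.053 to 0.27. Signal over background limits dim genes: the probe of DLX6 was well above background in 5 of 6 female-biased and 2 of 7 male-biased hens.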

Other observations

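The list of ovulatory genes described first was chosen after its values were seen, as was the test that leaves members of fixed lists out of the second list. In hen54, hen98 and hen102, several genes that granulosa cells switch on after the luteinizing hormone (LH) surge had low signals. PGR was at -0.90, -4.14 and -5.41 in these hens, against 1.57 to 3.33 in the other 12, as log2 values relative to the array's 75th percentile. TNFAIP6, which stabilises the matrix around the ovulating oocyte, was at -3.33, -2.56 and -4.06 against 2.02 to 4.30, PDE4B at -6.41, -7.41 and -7.79 against -1.93 to 0.92, and PTGS2 at 1.88, 1.07 and 1.03 against 3.73 to 5.98. RGS2 separated hen98 and hen102 (-0.83 and -0.35) from hen54 (5.54) and the others (5.89 to 7.16). STAR was at 4.44, 2.30 and 1.78 against 4.91 to 6.03. CREM was at 0.83, -2.10 and -2.55 against 1.78 to 3.71. AREG, EGR1, RUNX1 and RUNX2 did not separate the 3 hens. These genes came from a list put together after their values had been seen, 10 of whose 12 measured members had loadings away from the 3 hens, so its percentile of 0 among 10000 random lists matched on mean expression decides nothing.

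A hypothesis is that the F1 follicles of these 3 hens were collected before the LH surge and those of the other 12 after it. It was tested on a second list of 17 ovulatory genes, written from general knowledge with its threshold. None of their own values had been printed, but FOSL2, VCAN and NFIL3 belong to fixed lists whose scores had been seen. Of the 17, 6 were measured (FOSL2, VCAN, CITED2, SIK1, NFIL3 and SPRY2), all 6 had loadings away from the 3 hens, and their median loading lay at percentile 0.43 of 10000 matched lists, under the bound of 5. The matched lists were genes drawn at random. Genes that vary together for any reason pass such a bound more easily, so the percentile is no measure of chance. NFIL3 was at -1.56, -3.09 and -3.08 in the 3 hens against -0.30 to 1.39 in the others, FOSL2 at -5.64, -5.66 and -5.20 against -4.51 to -2.27, and SIK1 at -0.31, -1.35 and -1.04 against -0.06 to 2.79, while VCAN, CITED2 and SPRY2 overlapped the others. With FOSL2, VCAN and NFIL3 left out, the median loading of the other 3 genes lay at percentile 6.64, above the bound of 5. All 3 had loadings away from the 3 hens, so a list of 3 genes just above the bound neither carries the hypothesis nor excludes it. It stays open, no other cause of low signals of these genes was tested, and the labels analysed here give no time of collection.

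Both hen98 and hen99 carry opposite labels in their title and description. Their scores were -1.31 for hen98 and 0.45 for hen99 for theca and stroma markers, and 0.16 and 0.75 for oocyte and germ cell markers, relative to the mean of 15 hens. These values were not used to assign either hen.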
